A study of Homo sapiens with 12 samples.

How the data were processed

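RNA abundance was measured in 12 libraries of HT1080 cells, 2 for each of 6 groups. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with the Illumina TruSeq RNA kit. Reads were mapped with TopHat 1.4.0 and Bowtie 0.12.7 to GRCh37 and counted with HTSeq, per the submitters' processing notes; the version of HTSeq, its overlap mode and its strand setting are not given in the sources used here. The authors deposited 1 table of whole-number read counts per Ensembl gene, not normalized, with 36502 genes, their symbols and their GRCh37 positions; 59 genes carried no annotation. Since the use of strand is not stated, reads of a gene and an overlapping antisense gene cannot be told apart, and genes with near-identical copies are uncertain. Total counts ranged from 18774905 to 24827396 per library.

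The groups, comparisons, gene lists, tests and most alternatives were fixed before the data were examined. Genes were kept by edgeR's filterByExpr, which left 17262, and scaled by TMM. A quasi-likelihood model with 1 coefficient per group was fitted to all 12 libraries (6 residual degrees of freedom), with robust dispersions, in edgeR 4.0.16 under R 4.3.3. The 7 comparisons were the tracer against uninduced and the tracer with Dam-LaminB1 against the tracer in each clone, the difference between clones in each of these, and the uninduced clones against each other. P-values were adjusted by Benjamini-Hochberg at a threshold of 0.05. The SE of an edgeR log2 change was the absolute change divided by the square root of its F statistic. CPM values were scaled by TMM, and log2 CPM used a prior count of 2.

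The 30 gene lists covered the nuclear lamina, H3K9 methylation, interferon, p53 targets, integrated stress, ER chaperones, heat shock, mitochondrial and nuclear respiratory genes, cholesterol, G1/S, G2/M, immediate-early genes, NF-kB, extracellular matrix, hypoxia, DNA repair, fibroblast, epithelial, blood and neural markers, histones, ribosomal proteins, olfactory and taste receptors, keratin-associated proteins with defensins, cancer-testis antigens, zinc fingers, HOX genes, clustered protocadherins and neural adhesion genes. Each was tested with limma 3.58.1's camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. None of the camera calls held with the estimated correlation, and fry called 1 list, the neural markers between the clones (adjusted p = 0.041). The 11 lists called in no comparison without the block had smallest camera adjusted p from 0.074 (epithelial markers) to 0.54 (keratin-associated proteins with defensins); ER chaperones (0.085), mitochondrial genes (0.27), blood markers (0.34), histones (0.18), cancer-testis antigens (0.23) and neural adhesion genes (0.085) lay between. Of these, ER chaperones and histones passed only under the block. Genes were named by rule: up to 10 per direction and comparison with an adjusted p under 0.05, the largest change, a mean of at least 1 CPM, no overlap between replicates and a symbol, up to 4 members per list by smallest p, and LMNB1, EHMT1 and EHMT2. The members of lists given per library for the GFP clone were chosen after their values were seen.

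Library titles reuse 6 index sequences in 2 sets of 6 libraries. Deviations from group means correlated within a set over all 15 pairs of groups (0.41 to 0.86), so the sets appear to pair the libraries. The main fit, fixed beforehand, does not use this pairing, and values given without mention of the block ignore it. The fit with the index set as a block is given where it changes a call. Replicates were not duplicates: their counts differed with a chi-square per degree of freedom from 19.6 to 126.4. Alternatives were RLE factors, DESeq2 1.42.0, limma-voom, other count filters, only the groups compared, the block, leaving out each library (for lists also with the block, chosen after seeing the data) and a test against a fold of 1.5. The closing section gives their effect. For detected genes, libraries were thinned to 18774905 counts, with the mean of 10 draws. The scripts were tested on simulated counts that kept the fitted clone and index-set differences, with 65, 64 and 67 tested genes changed by 1.5-, 2- and 4-fold: over 16973 genes of the Dam-LaminB1 comparison in the VP16 clone, the model made 0 false calls, and 2 with the block. Counting intervals cover counting error only.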

Results

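RNA was sequenced from 2 clones of HT1080, a human fibrosarcoma cell line, that carry inducible reporters of contact between chromatin and the nuclear lamina. One clone expresses the m6A-Tracer, a GFP fusion that binds adenine-methylated DNA (the GFP clone). The other expresses a version fused to the VP16 activation domain (the VP16 clone). Each clone was grown in 3 conditions: uninduced, with doxycycline at 50 ng/ml for 4 days; tracer, with doxycycline for 3 days and then 24 h without it; and tracer with Dam-LaminB1. The last received the same treatment with 500 nM Shield1, which stabilises the methyltransferase fused to lamin B1. The groups are called GFP_uninduced, GFP_tracer, GFP_tracer_Dam, VP16_uninduced, VP16_tracer and VP16_tracer_Dam. With 2 libraries in each of the 6 groups there were 12 libraries, holding 18774905 to 24827396 counted reads each over 36502 genes. Nothing in the labels says whether the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

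The libraries fell into 2 sets of 6, one library of each group in each, that reused the same 6 index sequences, here called index sets 1 and 2. Libraries of one index set deviated together from their group means, with correlations across genes from 0.41 to 0.86 over the 15 pairs of groups. The first principal component, with 45.4% of the variance, set apart the GFP_tracer library of index set 1 at -78.2 and the GFP_tracer_Dam library of index set 1 at -87.0, while GFP_uninduced of that set lay at -16.2. The second component, with 25.1%, separated the clones within each set.

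**Figure D1:**
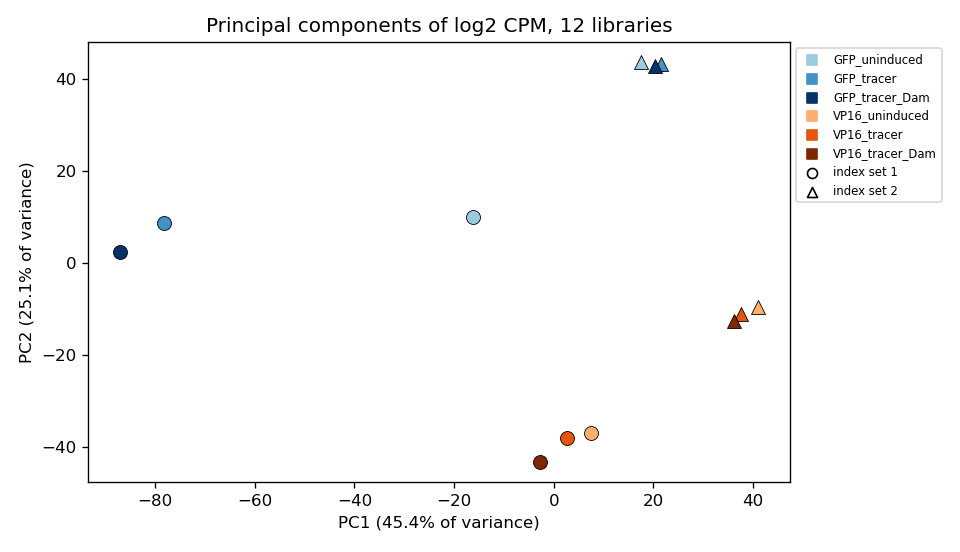
Principal components of the 12 libraries, with PC1 on the x axis and PC2 on the y axis, coloured by group and shaped by index set. The GFP_tracer and GFP_tracer_Dam libraries of index set 1 lie at -78.2 and -87.0 on PC1, apart from the other libraries.

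The clones were compared in the uninduced state to measure the background on which the induction experiments were run. Each tracer was carried by 1 clone, so effects of the clone, of the construct and of tracer expressed without induction cannot be told apart. Clone and construct cannot be told apart in the differences in response given below either. NOS1, the neuronal nitric oxide synthase, stood at 68.6 ± 14.8 CPM in VP16_uninduced against 3.58 ± 1.34 in GFP_uninduced (SD, n = 2 each), a log2 difference of 4.26 ± 0.48 (SE, edgeR adjusted p = 0.016). MAGEC1, a cancer-testis antigen, stood at 14.2 ± 0.41 CPM against 1.67 ± 0.39, and CSGALNACT1, an enzyme of chondroitin sulfate synthesis, at 34.8 ± 3.15 against 10.7 ± 0.01 (SD, n = 2 each). In the other direction, WBSCR17, a GalNAc-transferase, was at 27.4 ± 2.04 CPM in GFP_uninduced and at 1.36 ± 0.01 in VP16_uninduced, a log2 difference of -4.32 ± 0.19 (SE, edgeR adjusted p = 8.5e-05). GABBR2, a GABA-B receptor subunit, was at 32.3 ± 5.19 against 0.99 ± 0.37 CPM (SD, n = 2 each). In all, 48 of 17262 genes tested passed, 13 higher and 35 lower in the VP16 clone. With the index set as a block 327 did, 82 higher and 245 lower, with all 48 among them.

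Genes higher in the VP16 clone by the rule for named genes were also ZNF71, ONECUT3, CD74 (the MHC class II invariant chain), CMKLR1, TESPA1, NID2 (nidogen 2, a basement membrane protein) and GALR1, a galanin receptor. GALR1 had 216 counts in VP16_uninduced and 1 in GFP_uninduced, a ratio of 248 with a counting interval from 44.0 to 9822 (95%, exact binomial, counting error only). Genes lower in the VP16 clone included GAP43, NRCAM and SH3GL3, which are known from neurons, the extracellular matrix gene FRAS1, and GHR, the growth hormone receptor, with log2 differences of -4.49 ± 0.67, -3.84 ± 0.34, -3.96 ± 0.42, -3.82 ± 0.50 and -3.66 ± 0.28 (SE). The noncoding gene CTC-497E21.4 (chromosome 11, 12984057 to 13011095, GRCh37) differed by -4.99 ± 0.48 (SE), a value that is uncertain where genes overlap, since the strand setting is not known. CHRDL1, a BMP antagonist, had 770 counts in GFP_uninduced and 1 in VP16_uninduced, a ratio of 672 with an interval from 120.2 to 26574. The pseudogene CXADRP1 had 147 and 2 counts, and its reads could be shared with its parent gene, so its value is uncertain.

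**Figure D2:**
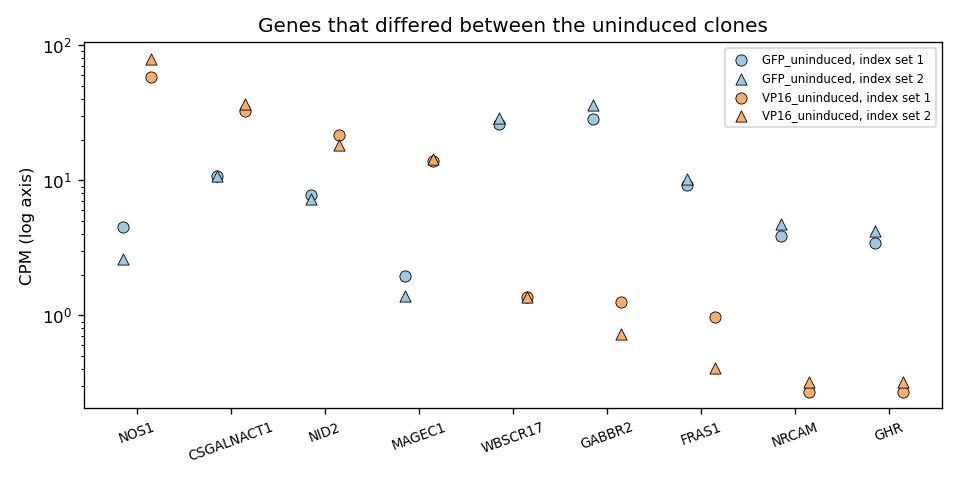
Level in CPM (y axis, log scale) of 9 genes that differed between the uninduced clones, with each point 1 library, coloured by clone and shaped by index set. NOS1, CSGALNACT1, NID2 and MAGEC1 were higher in the VP16 clone and WBSCR17, GABBR2, FRAS1, NRCAM and GHR higher in the GFP clone.

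Among the gene lists fixed before the data were examined, 5 of 30 passed the camera test between the clones. Each of the 5 calls ended when 1 uninduced library was left out without the block, which leaves the index sets unbalanced. With the block the interferon and p53 calls held with each of the 4 libraries left out in turn (largest camera adjusted p = 0.0057 and 0.0098) and the other 3 did not. Of 35 interferon-stimulated genes, 30 had a positive log2 difference, with a median of 0.55 (camera adjusted p = 0.0075, and adjusted p = 0.95 with an estimated correlation). No interferon gene passed over all genes or adjusted over the list alone. With the index set as a block 9 were higher, or 13 higher and 1 lower adjusted over the list alone. The interferon median was 0.92 in index set 1 and 0.19 in index set 2. BST2 (tetherin) was at 27.2 ± 11.7 against 3.64 ± 1.44 CPM and IFI44 at 33.1 ± 21.1 against 7.50 ± 6.15 (SD, n = 2), with edgeR adjusted p = 0.0034 and 0.0016 under the block. Of 26 p53 targets 4 had a positive value, with a median of -0.23 (camera adjusted p = 0.0076, and adjusted p = 0.95 with an estimated correlation); 1 member was lower adjusted over the list alone, and under the block 3 were lower, or 5 adjusted over the list alone, with ZMAT3 at -0.79 (edgeR adjusted p = 0.019 under the block). Of 32 clustered protocadherins 5 had a positive value, with a median of -0.43 (camera adjusted p = 0.0076, and adjusted p = 0.95 with an estimated correlation), and 1 member was higher and 2 lower adjusted over the list alone. PCDHGA12 differed by -2.90 ± 0.42 (SE, edgeR adjusted p = 0.042), although its 3' exons are shared with other members of the cluster and its counts are uncertain. Immediate-early genes had a median of 0.30 (camera adjusted p = 0.0097, and adjusted p = 0.95 with an estimated correlation) and neural markers one of -0.20 (camera adjusted p = 0.044, and adjusted p = 0.64 with an estimated correlation), with 2 of 7 lower adjusted over the list alone and GAP43 over all genes. The neural call ended under the block (camera adjusted p = 0.092). With the block the immediate-early median was 0.10 without VP16_uninduced replicate 2 (camera adjusted p = 0.28), and the protocadherin median was -0.22 without GFP_uninduced replicate 2 (camera adjusted p = 0.10). Most of the gene calls between the clones were lost in each fit without the block that leaves out 1 uninduced library.

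Removal of doxycycline in the GFP clone was examined for an effect of inducing the tracer without Dam-LaminB1. Tracer expression and doxycycline withdrawal change together in every group, so their effects cannot be told apart in either clone. The 2 index sets differed: ATF4 targets of the integrated stress response had a median log2 change of 1.78 in index set 1 and -0.09 in index set 2. DDIT3 (CHOP) went from 6.79 to 93.6 CPM, ASNS (asparagine synthetase) from 56.3 to 340.9 and CHAC1 (a glutathione-degrading enzyme) from 2.31 to 81.1 in index set 1, against 5.38 to 4.74, 75.8 to 66.9 and 6.97 to 4.64 CPM in index set 2. NF-kB targets and cytokines had medians of 1.39 and -0.05 in the 2 sets, with IL8 at 7.81 and 65.3 CPM in index set 1. G1/S genes had medians of -1.36 and 0.14. No gene of 17262 passed with edgeR, and 125 had an unadjusted p under 0.05 where chance gives 863.1. So few values point to a fit that overstates the spread, with a median SE of 0.29, against 0.21 with the index set as a block. The count of 0 therefore does not show that no gene changed, here or in the other induction comparisons below. DESeq2 and limma-voom also called 0, and so did the fit with the index set as a block. They had 134, 104 and 385 genes at an unadjusted p under 0.05, again fewer than chance gives. All hold the GFP libraries of index set 1 that PC1 set apart, so their counts of 0 do not show an absence of change either.

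**Figure D3:**
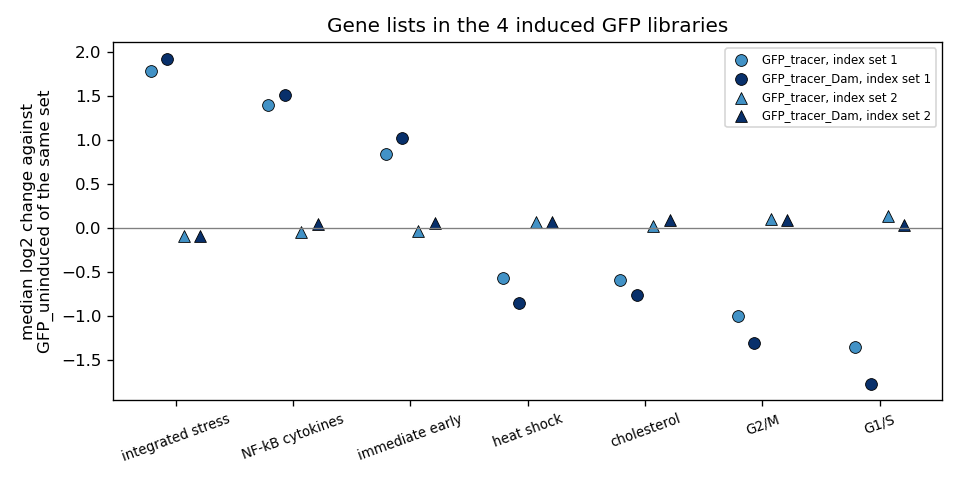
Median log2 change of 7 fixed gene lists (x axis) in the 4 induced GFP libraries against GFP_uninduced of the same index set (y axis). In index set 1 the integrated stress list stood at 1.78 and 1.92 and the G1/S list at -1.36 and -1.78, while in index set 2 they stood at -0.09 and -0.09 and at 0.14 and 0.03.

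By camera, 11 of 30 lists passed in this comparison, all with adjusted p from 0.77 to 0.80 with an estimated correlation. The integrated stress list (36 of 38 members positive, median 1.08, camera adjusted p = 1.1e-10, and adjusted p = 0.77 with an estimated correlation), the NF-kB list (21 of 23, median 1.01, camera adjusted p = 0.00016) and the immediate-early list (24 of 27, median 0.45, camera adjusted p = 3.7e-05) were higher. Cholesterol synthesis (0 of 23 positive, median -0.29), the 30 G1/S genes (median -0.45), the 30 G2/M genes (median -0.33), heat shock genes (median -0.20), HOX genes (median -0.26), nuclear respiratory chain genes (median -0.11) and ribosomal proteins (median -0.07) were lower, and the zinc finger list was higher (median 0.09, camera adjusted p = 0.030, and 0.055 under the index-set block). Under the block the replication-dependent histones passed as higher (camera adjusted p = 0.041, and adjusted p = 0.73 with an estimated correlation). Of the 11 calls 9 ended or turned when 1 library was left out, with the block as without it. Without GFP_tracer replicate 1 and with the block, the median was 0.03 for the integrated stress list, 0.14 for NF-kB, -0.12 for G1/S and -0.09 for G2/M (camera adjusted p = 0.66, 0.34, 0.57 and 0.64). Without the block, where the index sets are then unbalanced, the G2/M median was 0.19 and called in the other direction (camera adjusted p = 0.025). The respiratory chain list was still called with any 1 library left out (largest camera adjusted p = 0.0065, and 0.00030 with the block), as were the ribosomal proteins (0.0097, and 0.0014 with the block).

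Removal of doxycycline in the VP16 clone was examined for an effect of inducing the tracer with VP16, together with that of the withdrawal itself. Of 35 interferon-stimulated genes 34 had a positive log2 change, with a median of 0.41 (camera adjusted p = 0.00029, and adjusted p = 0.92 with an estimated correlation). The median was 0.53 in index set 1 and 0.13 in index set 2, and with the index set as a block the list passed with camera adjusted p = 4.8e-10 (adjusted p = 0.70 with an estimated correlation). IFITM1, a restriction factor at the cell surface, had a log2 change of 1.08 ± 0.47 and IRF9, a subunit of the interferon-activated transcription factor ISGF3, of 0.46 ± 0.37 (SE). Clustered protocadherins were positive in 29 of 32 (median 0.30, camera adjusted p = 3.3e-05), HIF targets and glycolysis genes in 20 of 28 (median 0.11, camera adjusted p = 0.0043), and ribosomal proteins in 2 of 78 (median -0.06, camera adjusted p = 1.3e-07), each with adjusted p = 0.77 with an estimated correlation. NDRG1, a HIF target, had a log2 change of 0.44 ± 0.29 (SE). Cholesterol synthesis genes (median 0.12, camera adjusted p = 0.035) and nuclear respiratory chain genes (median -0.03, camera adjusted p = 0.030) also passed, with adjusted p = 0.92 with an estimated correlation. The cholesterol call ended under the index-set block (camera adjusted p = 0.068).

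No gene passed in the VP16 clone with edgeR, with 72 at an unadjusted p under 0.05, and none with DESeq2, limma-voom or the index-set block over all 12 libraries. In a fit chosen after seeing the data, the 6 libraries of the VP16 clone with the block called 139 genes, 128 higher and 11 lower. Of the 6 list calls none held with each library left out in turn without the block. With it the protocadherins did, with medians from 0.19 to 0.42 (largest camera adjusted p = 0.039). The interferon median stayed positive with the block, at 0.10 without VP16_tracer replicate 1 (camera adjusted p = 0.19) and from 0.27 to 0.56 without another library, where it was called. Without the block and without VP16_tracer replicate 1 it was -0.62 (camera adjusted p = 0.0071). That fit sets a tracer library of index set 2 against uninduced libraries of both sets, and the list stood 1.31 higher in index set 1 over the 6 groups. With the block the largest camera adjusted p was 0.54 for ribosomal proteins, 0.51 for HIF targets, 0.62 for cholesterol synthesis and 0.63 for the respiratory chain. The 2 sets' fold changes correlated at r = 0.21 across 13935 genes in the VP16 clone and at -0.16 in the GFP clone, where genes are not independent replicates.

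Addition of Shield1 to stabilise Dam-LaminB1 was examined for its effect on expression in the presence of the tracer. Effects of Shield1 itself, of the lamin B1 fusion, of DNA methylation and of tracer bound to methylated DNA cannot be told apart. In the GFP clone both libraries of index set 1 in this comparison are the outlying ones, at -78.2 and -87.0 on PC1. All 30 G1/S genes had a negative log2 change (median -0.26, camera adjusted p = 9.8e-06, and adjusted p = 0.83 with an estimated correlation), with medians of -0.63 in index set 1 and -0.10 in index set 2. E2F1, which drives entry into S phase, had a log2 change of -0.47 ± 0.45 and MCM3, a replicative helicase subunit, of -0.35 ± 0.47 (SE). Extracellular matrix genes were positive in 28 of 32 (median 0.16, camera adjusted p = 9.8e-06, and adjusted p = 0.53 with an estimated correlation), with FBN1 (fibrillin 1) at 0.22 ± 0.11 and MMP2 at 0.35 ± 0.20 (SE). Fibroblast markers (median 0.25), HIF targets (0.09), HOX genes (0.12) and clustered protocadherins (0.18) were higher and DNA repair genes (-0.11) lower by camera, with adjusted p from 0.53 to 0.83 with an estimated correlation. In index sets 1 and 2 the medians were 0.25 and 0.07 for matrix genes, 0.34 and 0.07 for fibroblast markers, 0.20 and 0.02 for HIF targets, 0.21 and 0.01 for HOX genes, 0.18 and 0.17 for protocadherins and -0.27 and 0.01 for DNA repair. With the index set as a block 12 lists passed: interferon genes (camera adjusted p = 0.0016), p53 targets (0.0045) and ER chaperones (0.045) were gained as higher and heat shock genes (0.0497) and histones (0.045) as lower, with adjusted p from 0.56 to 0.76 with an estimated correlation. No gene passed with edgeR, with 80 at an unadjusted p under 0.05, and none with DESeq2, limma-voom or the block. None of the 7 list calls held with each library left out in turn, with or without the block. Without GFP_tracer_Dam replicate 1 and with the block, the G1/S median was 0.31 and the DNA repair median 0.19, both called in the other direction (camera adjusted p = 0.00011 and 0.00074). The matrix median was then -0.07 (camera adjusted p = 0.65) and the protocadherin median 0.02 (camera adjusted p = 0.48). That fit keeps the outlying GFP_tracer library without its outlying partner, which the block does not balance. Without GFP_tracer replicate 2 the G1/S median was 0.23 with the block (camera adjusted p = 0.82) and 0.62 without it (camera adjusted p = 0.026), where the index sets are unbalanced.

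In the VP16 clone 2 lists passed by camera for the same addition. Extracellular matrix genes were positive in 26 of 32 (median 0.05, camera adjusted p = 0.017) and ribosomal proteins in 4 of 78 (median -0.05, camera adjusted p = 1.4e-07), both with adjusted p = 0.98 with an estimated correlation. With the index set as a block 4 lists passed, with p53 targets gained as higher (21 of 26 positive, camera adjusted p = 0.00079, and adjusted p = 0.74 with an estimated correlation) and G1/S genes as lower (2 of 30 positive, camera adjusted p = 0.026, and adjusted p = 0.96 with an estimated correlation). THBS1 (thrombospondin 1) had a log2 change of 0.56 ± 0.28 and FBN1 of 0.19 ± 0.11 (SE). No gene of 17262 passed with edgeR, with 53 at an unadjusted p under 0.05, and none with DESeq2, limma-voom or the block over all 12 libraries. The 6 libraries of the VP16 clone with the block, a fit chosen after seeing the data, called 13 genes, 5 higher and 8 lower. The matrix call ended without VP16_tracer_Dam replicate 1 (camera adjusted p = 0.26) and, with the block, without VP16_tracer replicate 1 (0.39). The ribosomal call held with each library left out (largest camera adjusted p = 0.038, and 0.0024 with the block). In counts simulated for this comparison over 16973 genes, 54.7% of 53 genes at 1 CPM or more changed by 4-fold were recovered, and 1.82% of 55 changed by 2-fold; with the block the shares were 88.7% and 41.8%.

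LMNB1, the gene of lamin B1, was measured because the Dam-LaminB1 transgene carries its sequence. Shield1 acts on the protein, so these values do not show whether transgene reads were counted on LMNB1. It stood at 178.6 ± 14.9 CPM in GFP_uninduced, 119.7 ± 117.1 in GFP_tracer and 111.5 ± 116.0 in GFP_tracer_Dam (SD, n = 2 each). It stood at 175.9 ± 14.5, 165.6 ± 20.3 and 149.0 ± 38.5 in the VP16 groups in the same order. The wide spread in the GFP clone came from index set 1, where LMNB1 went from 168.1 to 36.9 and 29.5 CPM, against 189.1, 202.5 and 193.5 in index set 2. On Shield1 its log2 change was -0.10 ± 0.85 in the GFP clone and -0.15 ± 0.85 in the VP16 clone (SE). Both SE rest on the spread over all 12 libraries, so that of the VP16 clone includes the spread of the GFP libraries. EHMT2 (G9a), an H3K9 methyltransferase, had log2 changes of -0.16 ± 0.40 and 0.06 ± 0.40, and its partner EHMT1 of -0.01 ± 0.25 and 0.05 ± 0.25 (SE).

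**Figure D4:**
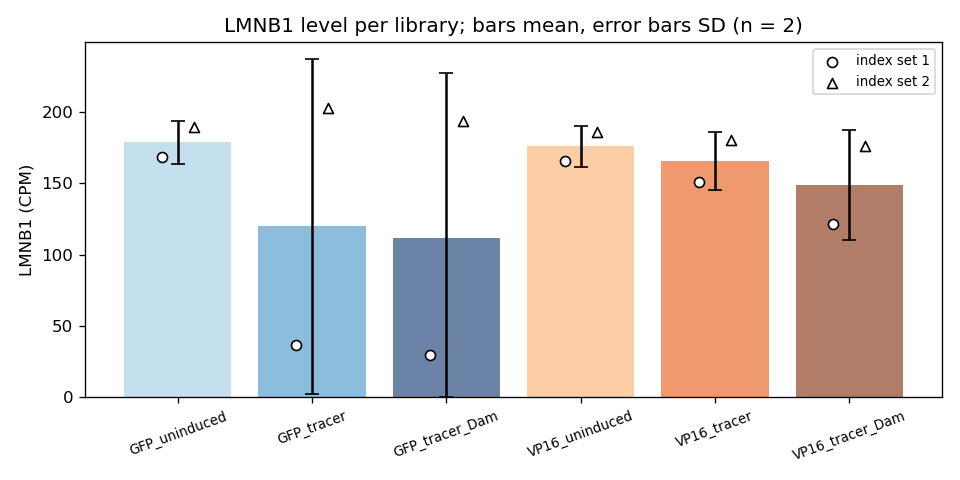
LMNB1 level in CPM (y axis) in the 6 groups, with bars at the mean of 2 libraries, error bars of 1 SD and points for each library shaped by index set. GFP_tracer and GFP_tracer_Dam of index set 1 stand at 36.9 and 29.5 CPM.

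The clones were then compared for the difference in their responses. For Shield1, no gene passed with edgeR (50 at an unadjusted p under 0.05) and 0 of 30 lists passed. The fold changes of the clones correlated at r = 0.29 across 13935 genes, but within index sets the value was 0.34 for set 1 and 0.08 for set 2. For doxycycline removal no gene passed (94 at an unadjusted p under 0.05), DESeq2 and limma-voom called 0 in both differences, and 11 lists passed by camera. Among them the integrated stress list differed by -1.13 in the median, VP16 minus GFP clone, and cholesterol synthesis by 0.44 (camera adjusted p = 8.1e-08 and 3.1e-07), with adjusted p = 0.84 for both with an estimated correlation. The integrated stress difference was -1.90 in index set 1 and 0.18 in index set 2, and each of the 11 calls ended or turned when 1 library was left out, with the block as without it (integrated stress camera adjusted p = 0.79 and 0.86 without GFP_tracer replicate 1). Without that library the G2/M difference was -0.03 with the block (camera adjusted p = 0.77) and -0.30 without it (camera adjusted p = 0.0062), where the index sets are unbalanced. Under the block 13 lists passed, with interferon genes gained as higher (camera adjusted p = 0.033) and histones as lower (0.013), with adjusted p = 0.79 and 0.69 with an estimated correlation. Since no gene was called in either clone for either treatment with edgeR over all 12 libraries, an overlap of calls could not be examined.

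Genes of the lamina and of H3K9 methylation, and gene families and regions that are often repressed, were examined as groups. Neither the 18 genes of the lamina and inner nuclear membrane (median log2 changes from -0.09 to 0.09 over the 7 comparisons, smallest camera adjusted p = 0.15) nor the 21 genes of H3K9 methylation (-0.08 to 0.06, 0.45) nor the 24 olfactory and taste receptors tested (-0.30 to 0.13, 0.085) passed in any of these 7 comparisons. The 32 clustered protocadherins passed in 4 of them and the 441 zinc finger genes in 2, with a smallest adjusted p = 0.77 with an estimated correlation. The lamina range averages unlike index sets: for the GFP tracer the lamina median was -0.25 in set 1 and 0.04 in set 2. In set 1, 14 of the 18 lamina genes were lower than in GFP_uninduced in both induced GFP libraries. Genes with the fewest neighbours within 500 kb, those with the most, and the genes of chromosomes 18 and 19 gave 0 calls in 28 tests (smallest camera adjusted p = 0.14). In 3 equal groups of genes by expression, median log2 changes lay between -0.03 and 0.04 in the 4 inductions. The genes detected at equal depth numbered 25646 ± 296 in GFP_uninduced, 25840.5 ± 1055 in GFP_tracer and 25933.5 ± 1158 in GFP_tracer_Dam. They numbered 24924.5 ± 535 in VP16_uninduced, 25167 ± 621 in VP16_tracer and 25471 ± 768 in VP16_tracer_Dam (SD, n = 2 each). In the VP16 clone the order was the same within each index set, 25303, 25606.6 and 26013.6 in set 1 and 24545.9, 24727.9 and 24928 in set 2. In the GFP clone it was 25855.6, 26586.5 and 26752.2 in set 1 and 25436.5, 25094.6 and 25114.7 in set 2.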

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

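The tests on the stress pattern in the GFP clone other than that of GC content and transcript length were chosen after the result was seen. The response to doxycycline removal differed between the clones, by a test of the difference itself, for 11 gene lists. The median differences, VP16 minus GFP clone, were -1.13 for integrated stress, 0.0629 for nuclear respiratory chain genes, 0.44 for cholesterol synthesis, 0.31 for G1/S, 0.23 for G2/M, -0.44 for immediate-early genes, -0.95 for NF-kB and cytokines, 0.19 for HIF targets and glycolysis, -0.10 for zinc fingers, 0.27 for HOX genes and 0.24 for clustered protocadherins. None passed with an estimated correlation (adjusted p from 0.84 to 0.86), and none of the 11 calls held with each library left out in turn, with or without the index set as a block (without it, largest camera adjusted p from 0.076 for G1/S to 0.91 for HOX genes).

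The difference in integrated stress was -1.90 in index set 1 and 0.18 in index set 2. That in protocadherins was 0.21 and 0.27 and that in HIF targets 0.28 and 0.15, and these calls ended too when 1 library was left out (largest camera adjusted p = 0.90 and 0.47, and 0.23 and 0.33 with the block). In index set 1 of the GFP clone, GFP_tracer and GFP_tracer_Dam both held high stress and cytokine genes and low cell cycle genes. An effect of tracer induction is argued against as the whole cause by index set 2, where the integrated stress list had a median of -0.0892 with a member SD of 0.168 on tracer induction, and of -0.09 with Dam-LaminB1. A swap with VP16 libraries is argued against by 19 of the 20 named clone genes, which lay nearer to the uninduced GFP mean in both libraries. Removing the trend on GC content and transcript length left the median at 1.83, from 1.78 before. A difference in the culture of these dishes may be the source and stays open, since the labels record none.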

How the results depend on the processing

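The count between the uninduced clones was 48 and moved to 23 tested against a fold of 1.5, 220 with no low-count filter, 327 with the index set as a block, 1 with only the groups compared (fewer libraries), 30 with limma-voom and 267 with DESeq2. With RLE factors it was 49 and with the stricter filter 53. The counts of 0 in the other 6 comparisons stayed at 0 under all these. Leaving out 1 library gave 1 to 5 between the clones, 0 to 1 for the tracer in the GFP clone, 0 to 1 for Shield1 in the GFP clone, and 0 elsewhere; the lone library left in a group is assumed to vary like the other groups, and the index sets are then unbalanced. Chosen after seeing the data, removal of GFP_tracer replicate 1 and GFP_tracer_Dam replicate 1 gave 129 between the clones and 0 elsewhere. With the block as well it gave 3685 between the clones, 0 for the clone difference in the tracer effect and 1 in each of the other 5: PTGES for the tracer and H1F0 for Shield1 in the VP16 clone, and MIR663B in the rest, each looked up after its call was seen. The 6 libraries of a clone with the block gave 139 genes for the tracer and 13 for Shield1 in the VP16 clone, and 0 in the GFP clone. Among the list results, 42 lost their call with an estimated correlation, 41 with fry, 13 with no low-count filter and 3 with the block, which also added 10 calls (adjusted p from 0.56 to 0.96 with an estimated correlation). With those 2 libraries removed 10 lost their call and 16 turned, and with the block as well 13 and 14. Of 42 list calls, 39 ended or turned without at least 1 library and 3 held throughout: the respiratory chain and ribosomal proteins for the GFP tracer and ribosomal proteins for Shield1 in the VP16 clone. Of those that turned, 5 were then called in the other direction. With the block, added after seeing the data, 6 held with each library left out, 10 turned and 2 of these were called in the other direction. In the fits without the block, most were lost without GFP_tracer replicate 1, where 8 ended and 14 turned. In the same fits 10 ended without GFP_uninduced replicate 2, and 9 ended and 1 turned without VP16_uninduced replicate 2.

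With those 2 libraries removed, camera directions turned, with medians, for the GFP tracer to 0.0252 for integrated stress, 0.0341 for heat shock, 0.0248 for cholesterol, 0.12 for G1/S (adjusted p = 0.0011), 0.19 for G2/M (adjusted p = 3.2e-06), -0.0191 for immediate-early, -0.22 for NF-kB, -0.0255 for zinc fingers and 0.0793 for HOX, for Shield1 in the GFP clone to 0.01001 for DNA repair, for the clone difference in the tracer effect to -0.0243 for integrated stress, -0.23 for G1/S (adjusted p = 4.3e-08), -0.29 for G2/M (adjusted p = 5.8e-10), 0.00129 for immediate-early, 0.33 for NF-kB (adjusted p = 0.027) and 0.0159 for zinc fingers. With the block as well, they turned for the GFP tracer to -0.13 for integrated stress (adjusted p = 3.0e-11), 0.0243 for heat shock, 0.0622 for cholesterol (adjusted p = 0.049), 0.0606 for G1/S (adjusted p = 0.0043), 0.0718 for G2/M (adjusted p = 7.0e-05), -0.00459 for immediate-early and -0.0205 for zinc fingers, for Shield1 in the GFP clone to 0.01001 for DNA repair, for the clone difference in the tracer effect to 0.16 for integrated stress (adjusted p = 8.5e-07), -0.16 for G1/S (adjusted p = 3.1e-09), -0.15 for G2/M (adjusted p = 2.9e-11), 0.0754 for immediate-early, 0.0916 for NF-kB and 0.0205 for zinc fingers. Those with an adjusted p, 5 and 7 in number, passed camera in the direction opposite to that with all 12 libraries. The removal of these libraries itself shows their part in it.

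With each library left out in turn, for the GFP tracer medians ranged from -0.36 to 0.0818 for lamina, -0.26 to 0.0808 for H3K9, 0.0149 to 1.66 for integrated stress, -0.54 to 0.0299 for heat shock, -0.17 to -0.0593 for respiratory chain, -0.61 to 0.0203 for cholesterol, -1.29 to 0.12 for G1/S, -1.17 to 0.19 for G2/M, -0.0232 to 0.71 for immediate-early, -0.23 to 1.64 for NF-kB, -0.0983 to -0.0667 for ribosomal, -0.21 to 0.31 for olfactory, -0.0301 to 0.19 for zinc fingers, -0.78 to 0.0763 for HOX and -0.40 to 0.38 for protocadherins. For the VP16 tracer medians ranged from -0.0954 to 0.00404 for lamina, -0.10 to 0.0430 for H3K9, -0.62 to 1.19 for interferon, -0.0903 to -0.00449 for respiratory chain, 0.0150 to 0.17 for cholesterol, 0.0727 to 0.11 for HIF, -0.12 to 0.00725 for ribosomal, -0.0696 to 0.17 for olfactory, -0.0315 to -0.00741 for zinc fingers and -0.0466 to 0.57 for protocadherins. For Shield1 in the GFP clone medians ranged from -0.29 to 0.17 for lamina, -0.25 to 0.17 for H3K9, -1.48 to 0.62 for G1/S, -0.0843 to 0.35 for matrix, -0.10 to 0.26 for HIF, -0.60 to 0.31 for DNA repair, 0.0125 to 0.42 for fibroblast, -0.34 to 0.0550 for olfactory, -0.0657 to 0.16 for zinc fingers, -0.15 to 0.52 for HOX and -0.28 to 0.72 for protocadherins. For Shield1 in the VP16 clone medians ranged from -0.11 to 0.0697 for lamina, -0.0980 to 0.0957 for H3K9, 0.0526 to 0.16 for matrix, -0.0872 to -0.0428 for ribosomal, -0.18 to 0.0600 for olfactory, -0.0119 to 0.0119 for zinc fingers and -0.25 to 0.65 for protocadherins. For the clone difference in the Shield1 effect medians ranged from -0.18 to 0.26 for lamina, -0.17 to 0.18 for H3K9, -0.18 to 0.20 for olfactory, -0.15 to 0.0939 for zinc fingers and -0.61 to 0.59 for protocadherins. For the clone difference in the tracer effect medians ranged from -0.12 to 0.28 for lamina, -0.15 to 0.24 for H3K9, -1.68 to -0.0196 for integrated stress, 0.0152 to 0.15 for respiratory chain, 0.11 to 0.75 for cholesterol, -0.24 to 1.20 for G1/S, -0.30 to 1.11 for G2/M, -0.66 to -0.00586 for immediate-early, -1.51 to 0.33 for NF-kB, 0.0398 to 0.37 for HIF, -0.30 to 0.15 for olfactory, -0.18 to 0.00854 for zinc fingers, -0.0273 to 0.79 for HOX and -0.0109 to 0.68 for protocadherins. For the uninduced clones medians ranged from -0.0943 to 0.0997 for lamina, -0.00897 to 0.12 for H3K9, 0.14 to 1.00 for interferon, -0.53 to -0.0656 for p53, 0.27 to 0.36 for immediate-early, -0.60 to 0.14 for neural, -0.32 to -0.25 for olfactory, 0.0344 to 0.0800 for zinc fingers and -0.60 to -0.13 for protocadherins. All these ranges come from fits without the block, where leaving out a library unbalances the index sets. The count filter was applied anew in each fit, so list members could differ. A range therefore need not hold the value from all libraries. The depth limits genes of few counts, such as GALR1 in the GFP clone. Other causes were not tested.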

Other observations

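The comparison of VP16_tracer_Dam with VP16_uninduced was added after seeing the data and its genes were named after their values were seen, as were the tests in this part except those of GC content and of snoRNA and snRNA genes. Within the 6 VP16 libraries, with the index set as a block, 1573 of 16139 genes passed with edgeR, 900 higher and 673 lower. Interferon genes were higher, 18 of 35 members passing and 0 in the other direction (median 0.47), with OAS1, which activates RNase L, at 1.52 ± 0.12 (SE) and IFIT2 at 0.50 ± 0.07. Of 30 G1/S genes 22 were lower (median -0.27), among them MCM5 at -0.41 ± 0.05 and E2F1 at -0.51 ± 0.07 (SE), and of 32 extracellular matrix genes 15 were higher and 2 lower, with COL1A1 at 0.80 ± 0.11 and FN1 (fibronectin) at 0.52 ± 0.06. PTGES, a prostaglandin synthase, was higher at 0.82 ± 0.10, and the linker histone gene H1F0 lower at -0.39 ± 0.04. By camera these 3 lists had adjusted p = 2.0e-19, 3.6e-21 and 1.4e-09, and each had adjusted p = 0.47 with an estimated correlation. With an estimated correlation 0 of 29 lists passed, but that estimate rests on 2 residual degrees of freedom, so the 0 says little about them. In all 17 of the 29 lists passed by camera. Among them was the lamina and inner nuclear membrane list, lower with a median of -0.01 (camera adjusted p = 0.025, and adjusted p = 0.47 with an estimated correlation), where LMNB2 (lamin B2) at -0.21 ± 0.04, TMPO (LAP2) at -0.19 ± 0.05 and NUP153 (a nucleoporin) at -0.16 ± 0.05 (SE) were lower and 0 of 18 members higher.

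That count depends on the fit: the 6 libraries without the block called 0 genes, all 12 libraries called 0 with or without the block, and 56 passed with the block when the 2 outlying GFP libraries were removed. The fit of 1573 genes has 2 residual degrees of freedom. When the labels of the 2 groups were crossed in index set 2, 0 genes passed, which is no check on the count. Of the 1573 called genes 1571 moved the same way in both index sets, so crossing the labels sets their changes against each other. The GFP clone called 0 genes in the same kind of fit, with 337 at an unadjusted p under 0.05. That fit holds the outlying GFP_tracer and GFP_tracer_Dam libraries of index set 1, which widen its spread. It therefore does not show that the changes are particular to the VP16 clone. Doxycycline removal stays open: in the direction of their call, the called genes had a median change of -0.0136 in the GFP libraries of index set 2 and of 0.36 in those of index set 1. In the VP16 libraries, from which the genes were chosen, it was 0.18 and 0.35. Part of the change may be shared with the state of the outlying GFP libraries of index set 1. NF-kB (median 0.20), heat shock (-0.09), G1/S (-0.27) and G2/M (-0.12) genes moved in the VP16 comparison as in those libraries. Cholesterol synthesis genes (0.15) and histones (-0.26) moved the other way, and ER chaperones and HIF targets differed between those libraries. The integrated stress list had a median of -0.0643 in the VP16 comparison, which argues against their integrated stress response only. Whether the VP16 tracer with Dam-LaminB1 or the culture of these dishes moved the genes stays open.

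The index sets differed in 4869 of 17262 genes with edgeR, 2696 higher in set 1 and 2173 lower. In the 4 groups other than GFP_tracer and GFP_tracer_Dam, 6766 of 16553 did. Interferon genes were higher in set 1 in 6 of 6 groups (median 1.31), p53 targets in 6 of 6 (0.54), replication-dependent histones in 6 of 6 (1.11) and clustered protocadherins in 6 of 6 (0.56), while G2/M genes were lower in all 6 (-0.60). In those 4 groups the medians were 1.33 for interferon genes, 0.41 for p53 targets, 1.04 for histones, 0.48 for protocadherins and -0.24 for G2/M genes. The G2/M difference was thus largest where the outlying GFP_tracer and GFP_tracer_Dam libraries entered. Of all lists, the 7 keratin-associated and defensin genes moved most over the 6 groups (2.59, higher in 6 of 6). Blood markers were also higher in 6 of 6 (0.39), and lamina genes in 0 of 6 (-0.12). The mitochondrial share of counts was 3.65 to 4.00% in set 1 and 3.30 to 3.45% in set 2. Removing the trend on GC content and transcript length left the interferon median at 1.39. For weaker poly(A) selection in set 1, 69 snoRNA and snRNA genes had a median of -0.18 ± 0.05 (SE over genes), so they were not higher in set 1. Reads of host genes that overlap them may be counted on these genes, since the strand and overlap settings are not given. Weaker selection thus stays open for the histones. Such a weakness would not raise interferon mRNAs, which carry poly(A) tails. Their medians were 0.58 in the GFP and 1.37 in the VP16 uninduced libraries, which are part of the set difference itself and not a separate test. Culture day and library batch cannot be told apart, since the index set is the only record of either.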
